A study of Sus scrofa domesticus with 6 samples.

How the data were processed

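The data are droplet single-cell RNA libraries of pig lung, made with the DNBelab C Series HT kit and sequenced on a DNBSEQ-T7 instrument per the labels. The 6 libraries form 3 groups: control (3 libraries, unsorted cells of donors' right lungs per the labels), IRI CD45+ (2 libraries) and IRI CD45- (1 library). The deposited matrices hold counts, that is UMI counts per gene and cell without normalization; per the file headers they were written by the tool PISA. The submitters' processing notes name the genome build Sscrofa11.1, Seurat 5.5.3 and R 4.2.2; the aligner and the gene annotation are not given in the sources used here. Total UMIs per library ranged from 19098567 to 40647380. In simulated data at these depths the test found 17% of 2-fold and 67.0% of 4-fold changes in macrophage-like cells and 8.79% and 54.7% in endothelial-like cells.

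Matrices were read with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scanpy 1.11.5. An Ensembl identifier took a gene symbol only where the reference table paired it with a symbol that no other feature used (139 of 17062 identifiers). Cells were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. The IRI libraries list no mitochondrial gene, so the last limit could act only in the controls. Doublets were called per library with Scrublet at an expected rate of 6%; it called 3, 6 and 51 cells in the controls, 112 and 6 in the IRI CD45+ and 1 in the IRI CD45- library, far below that rate, so the removal of the top 6% of scores was added as an alternative after seeing the data. Counts were scaled per cell and logged for clustering only, and the 2000 most variable genes listed in both library sets gave 30 principal components, 15 neighbours per cell and a Leiden clustering (igraph 0.11.9) at resolution 1.0, with no integration across libraries. It gave 33 clusters from 40645 cells.

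Clusters were named from marker lists of 21 cell types written before the data were examined: the class with the highest mean marker fold, which had to reach 1.2 on the log2 scale with at least 3 markers above 2-fold. Clusters whose best classes lay within 0.5 were clustered again at resolution 0.5 (6 clusters split, 58 in all, 6 left unnamed). The rules that send a cluster to the unnamed class (more markers of another class among its top 10 genes, or a median UMI total under 0.5 of its library's with no own marker there) were revised after seeing the clusters. Unnamed cells made up 4.17%, 2.38% and 2.66% of the controls, 1.18% and 12.2% of the IRI CD45+ libraries and 0.96% of the IRI CD45- library. Names carry the ending "-like" because they rest on RNA alone.

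For each class, UMIs were summed per library, and a library entered with at least 20 cells of the class. Groups were compared with edgeR 4.0.16 (R 4.3.3; TMM normalization, filterByExpr, robust quasi-likelihood test), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Immune classes compared control with IRI CD45+ libraries, and structural classes control with the lone IRI CD45- library, which is assumed to vary like the controls. SE is the log2 change divided by the square root of F. CPM values are means over libraries after TMM scaling; those of single libraries, of summed controls and of free RNA are without it. Where a group had 0 UMIs, folds are lower bounds against a floor of 3 counts over the group; with 1 to 3 UMIs the ratio is given with its 95% counting interval. The difference between the macrophage-like and the T- or monocyte-like change was tested with limma 3.58.1 on per-library differences of log2 CPM (prior count 2). Shares of immune classes among immune-named cells were compared with 2-sided exact permutation tests. The edgeR test and the limma difference test were also run on simulated data.

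Named genes followed a rule written before the data were examined: in macrophage- and endothelial-like cells the 10 largest changes up and down among called genes with a symbol, a mean of at least 50 CPM in the higher group and no overlap between groups; a fixed set of ferroptosis, iron, adhesion and junction genes whatever their result; and up to 4 members with the smallest p from each list described (4 largest and up to 3 members in the other classes). Some genes that the rule picked are not reported here. Gene lists, 23 in all, were also written before the data were examined. They were tested with camera (limma; preset correlation 0.01) and with an estimated correlation, and with fry; the test needs at least 5 measured members. Members called are also counted with adjustment over the list alone.

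Free RNA of AT2- and secretory-like cells in the other classes of the IRI CD45- library was estimated by scaling those profiles to the SFTPC and SCGB1A1 levels of the class. Genomic spans came from the RefSeq table of Sscrofa11.1. The labels speak of pairs of lung specimens without saying which libraries pair, so replicate numbers were not used as a block; a fit with numbers 1 and 2 as a replicate block was an alternative. It called 829 genes higher and 1172 lower in macrophage-like cells, and the deviations of same-numbered libraries from their group means correlated across genes at -0.055 and -0.03 there. Other alternatives were DESeq2 1.42.0 size factors and its Wald test, no low-count filter, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), called doublets kept, Leiden resolutions 0.5 and 2.0, thinning of every library's class sum to the smallest sum, the union of the gene lists, macrophage- and monocyte-like cells together, and leaving out each replicate. In ciliated-like cells 2 controls entered, which leaves 1 residual degree of freedom. Chosen after seeing the data were the removal of the top 6% of doublet scores, genes counted in any IRI library, genes spanning under 50 kb, leaving out genes of which free epithelial RNA explains at least 0.33, cluster 13 only, and the IRI CD45- library added as an IRI library for macrophage-like cells. Alveolar, secretory and neutrophil-like cells were too few in the controls for a test.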

Results

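Lung cells of domestic pigs were profiled by droplet single-cell RNA sequencing in a model of single-lung transplantation, in which the graft was kept cold for 24 hours and then reperfused for 8 hours (ischemia-reperfusion injury, IRI). The series has 6 libraries. The 3 control libraries held the whole cell suspension of the donors' right lungs. The grafts gave 2 libraries of cells sorted for CD45, a surface protein of immune cells (IRI CD45+), and 1 library of cells sorted as lacking it (IRI CD45-). No control was sorted, so sort and injury cannot be told apart in any comparison. Control replicates 1, 2 and 3 held 25802239, 33549585 and 32573142 UMIs (unique molecular identifiers, each counting 1 captured transcript) in 4957, 6556 and 6365 cells. IRI CD45+ replicates 1 and 2 held 19435860 and 19098567 UMIs in 4922 and 4705 cells, and the IRI CD45- library held 40647380 UMIs in 15817 cells. The lowest total of any deposited cell was 1001 UMIs in each control, and 74, 115 and 117 UMIs in the IRI CD45+ and CD45- libraries. After filtering, 40645 cells remained, with a median of 2968.0, 3196.5 and 3121.0 UMIs per cell in the controls, 2941.0 and 2896.5 in the IRI CD45+ libraries and 1964.0 in the IRI CD45- library. All intervals and floors below cover counting error only.

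The lists of counted genes differed between the control and the IRI libraries. In all, 33025 genes were listed in at least 1 library and 23556 in all 6. The 13 protein-coding genes of the mitochondrial genome took 6.95%, 6.09% and 5.58% of UMIs in the controls and were listed in no IRI library. HMOX1, the heme-degrading enzyme heme oxygenase 1, and HSP90AA1, a stress-inducible chaperone, were likewise listed in every control and in no IRI library. They belong to 687 genes with that pattern, which took 14.5%, 11.4% and 11.0% of control UMIs. Of the 219 of them that the Sscrofa11.1 annotation names, 151 lie on unplaced scaffolds, against 0 of 12927 annotated genes listed in all 6 libraries. Each comparison used the genes listed in every library compared.

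PTPRC, the gene of CD45, tracked the sort. It was detected in 68.9% (95% exact Clopper-Pearson interval 67.5 to 70.3) and 63.6% (62.1 to 65.1) of the cells of the IRI CD45+ libraries and in 9.91% (9.44 to 10.4) of those of the IRI CD45- library. In the unsorted controls the shares were 51.8% (50.3 to 53.2), 47.0% (45.8 to 48.2) and 41.0% (39.8 to 42.3). With every cell thinned to 500 UMIs, the shares were 29.5% and 24.7% in the IRI CD45+ libraries, 4.04% in the IRI CD45- library and 16.6%, 15.2% and 13.1% in the controls. Cells named as structural types, which lack CD45, gave the background: 3.28% had a PTPRC UMI in the IRI CD45- library (12857 cells, median 2040.0 UMIs), and 5.45%, 5.49% and 3.89% in the controls (medians 3598.0, 3244.0 and 3396.0 UMIs).

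Immune-named cells made up 98.8% and 87.7% of the IRI CD45+ libraries, 13.3% of the IRI CD45- library and 85.2%, 74.7% and 65.4% of the controls. Clusters that no marker rule named held 1.18% and 12.2% of the IRI CD45+ libraries, 0.96% of the IRI CD45- library and 4.17%, 2.38% and 2.66% of the controls. In the IRI CD45- library, 8766 of 15016 cells (58.4%) resembled alveolar type 2 (AT2) cells, the surfactant-making epithelium, against 1, 1 and 3 such cells in the controls. Cluster 31 held 93 of them, and 2 of those in the controls, with no AT2 marker among its top 10 genes. The parts of clusters 11, 20, 27 and 30 named AT2-like (32, 133, 126 and 166 cells) also had markers of other classes there.

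The shares of immune classes among immune-named cells address which immune cells the injured graft held. Neutrophil-like cells, phagocytes that enter injured tissue from the blood, made up 23.8% ± 4.05 (SD, n = 2) in IRI CD45+ libraries and 0.122% ± 0.0604 (n = 3) in controls. Macrophage-like cells made up 1.02% ± 0.182 against 8.41% ± 1.99, and dendritic-like cells, which present antigen, 1.22% ± 0.584 against 5.84% ± 1.58. Antibody-secreting plasma-like cells made up 2.16% ± 0.0419 against 11.0% ± 3.08, and natural killer (NK)-like cells 20.4% ± 3.67 against 39.9% ± 2.70. Clusters 1, 2 and 7, which held most NK-like cells, also scored 2.25, 2.14 and 2.01 for T markers. Their NK scores were 2.81, 2.96 and 3.52 (mean log2 marker folds). Those T scores lay above the scores of clusters 12 and 29, which were named T-like (1.62 and 1.44). In clusters 1, 2 and 7, 12, 10 and 11 T markers were above 2-fold, beside 10, 10 and 9 NK markers. CD3D was among the leading genes of cluster 7. The class thus carried T as well as NK markers, and its share cannot be assigned to NK cells alone. T-like cells made up 33.9% ± 7.75 against 25.6% ± 0.956, and monocyte-like cells 5.38% ± 5.25 against 0.509% ± 0.192. For each of these 7 classes both IRI libraries lay outside the range of the controls. The 2-sided exact permutation p was 0.1, the smallest possible with 10 splits, and 0.129 after adjustment over 9 classes, so no share passed the test. B-like cells (10.6% ± 2.05 against 7.58% ± 1.61, exact permutation p = 0.3) and mast/basophil-like cells (1.54% ± 0.743 against 1.08% ± 0.288, exact permutation p = 0.5) overlapped between groups. Cells under 500 UMIs were removed before sharing out, but the controls held no cell under 1001 UMIs. The shares above thus compare groups cut at unlike UMI limits. A stricter cell filter (at least 1000 UMIs and 500 genes, at most 10% mitochondrial UMIs) set a like UMI limit. The neutrophil-like share was then 8.52% in the IRI CD45+ libraries and 0.1025% in controls. With a finer clustering it was 11.6% in the IRI CD45+ libraries. The T-like share was 39.4% in IRI CD45+ replicate 1 and 28.5% in replicate 2. The monocyte-like share was 1.67% in IRI CD45+ replicate 1 and 9.10% in replicate 2. With called doublets kept it was 1.37% and 7.53% against 2.35%, 1.44% and 0.862% in the controls, so the groups overlapped (exact permutation p = 0.3).

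**Figure D1:**
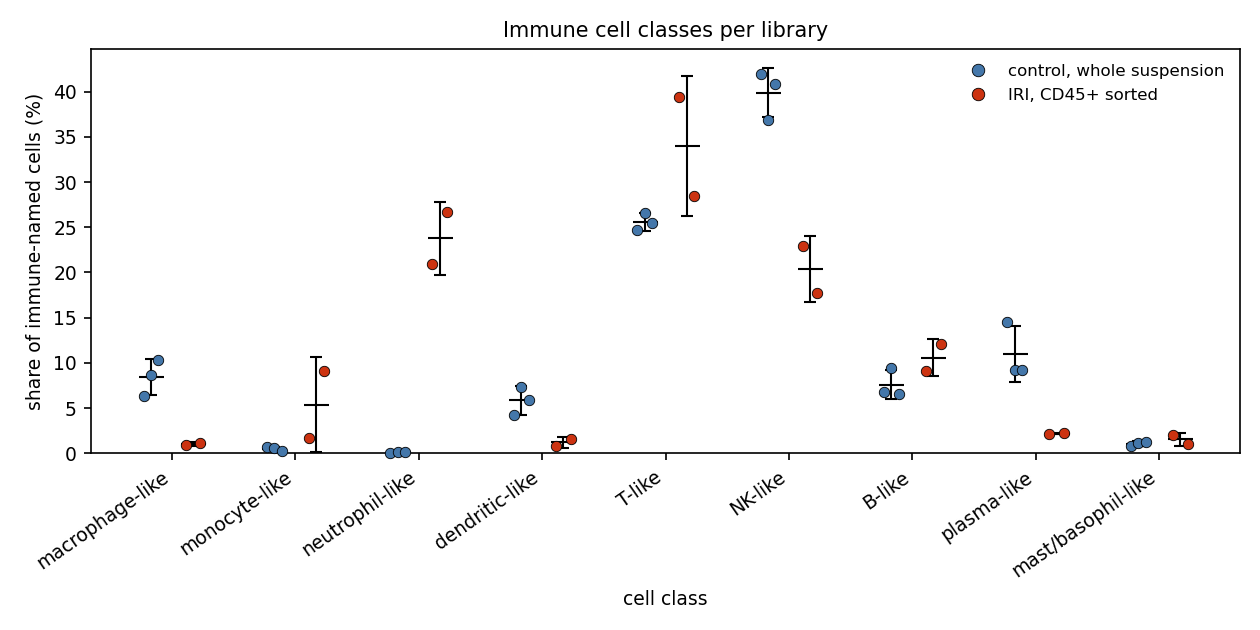
Share of immune-named cells (%, y axis) in each of 9 immune classes (x axis). Points are libraries, 3 controls and 2 IRI CD45+; black bars are the mean and SD. Neutrophil-like cells averaged 23.8% in IRI CD45+ libraries and 0.122% in controls, and macrophage-like cells 1.02% and 8.41%.

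The comparison of macrophage-like cells addresses ferroptosis, an iron-dependent cell death through lipid peroxidation, which the series' title names. ACSL4, the enzyme that loads membranes with the polyunsaturated lipids that peroxidize, rose from 121 ± 21.8 CPM (UMIs scaled to equal library totals after TMM normalization, SD, n = 3) in controls to 271 ± 24.3 CPM (n = 2) in IRI CD45+ libraries, a log2 change of 1.16 ± 0.22 (SE, edgeR adjusted p = 0.00253). LPCAT3, which inserts such lipids into phospholipids, fell from 44.0 ± 7.12 to 13.9 ± 10.04 CPM (log2 change -1.76 ± 0.46, adjusted p = 0.0142). PTGS2, a prostaglandin synthase often used as a ferroptosis marker, fell from 203 ± 52.8 to 109 ± 10.6 CPM (log2 change -0.90 ± 0.27, adjusted p = 0.0255). GPX4, the peroxidase that detoxifies lipid peroxides, stood at 250 ± 38.1 CPM in controls and 205 ± 44.2 CPM in IRI (adjusted p = 0.347). SLC7A11, the cystine importer upstream of GPX4, stood at 14.03 ± 2.91 and 30.1 ± 8.63 CPM (adjusted p = 0.0581). The iron genes FTL (ferritin light chain), TFRC (transferrin receptor) and NCOA4 (ferritin degradation) had log2 changes of -0.15 ± 0.20, 0.49 ± 0.33 and -0.78 ± 0.29 (adjusted p = 0.597, 0.281 and 0.0602). AIFM2, a GPX4-independent suppressor, and CD163, the hemoglobin scavenger receptor, also missed the threshold (adjusted p = 0.350 and 0.0566). HMOX1 reached 254 ± 58.4 CPM in controls (without TMM scaling) and was not counted in the IRI libraries, FTH1 had no feature of that name, and SLC40A1 had too few UMIs. In Sscrofa11.1, ACSL4 lies on chromosome X from 89760863 to 89838103, LPCAT3 on chromosome 5 from 63707674 to 63746369 and GPX4 on chromosome 2 from 77321568 to 77323931. The call of LPCAT3 was lost without IRI CD45+ replicate 1 (log2 change -1.10). That of PTGS2 was lost without control replicate 1, control replicate 3 or IRI CD45+ replicate 1 (-0.91, -0.65 and -0.82). Without IRI CD45+ replicate 2, SLC7A11 and NCOA4 passed (1.34 and -1.23).

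**Figure D2:**
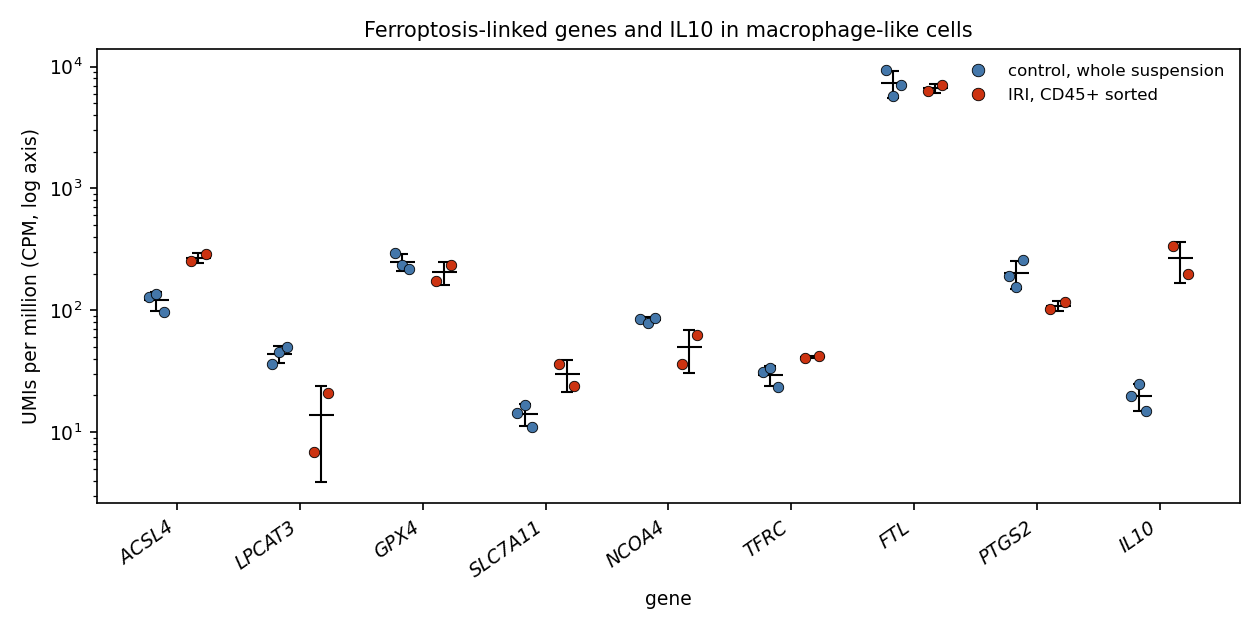
Scaled UMI counts (CPM, y axis, log scale) of 8 ferroptosis-linked genes and IL10 (x axis) in macrophage-like cells. Points are libraries, 3 controls and 2 IRI CD45+; black bars are the mean and SD. ACSL4 averaged 121 CPM in controls and 271 CPM in IRI, and GPX4 250 and 205 CPM.

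The fixed lists around ferroptosis moved in both directions. Of 28 measured ferroptosis drivers and markers, 7 rose, 4 fell and 17 were not called (8 and 7 adjusted over the list alone). The zinc and iron importer SLC39A14 rose by a log2 change of 2.41 ± 0.25, the glutamine importer SLC1A5 by 1.95 ± 0.20 and the heme-sensing repressor BACH1 by 1.83 ± 0.21, whereas the peptidase DPP4 changed by -3.13 ± 0.45. The list missed the competitive test (adjusted p = 0.0867, and 0.686 with an estimated correlation) and passed the self-contained one (fry adjusted p = 0.0152, up). Of 30 suppressors, 6 rose and 4 fell (8 and 4 adjusted over the list alone; adjusted p = 0.220). The chaperone HSPA5 (1.48 ± 0.17), the hyaluronan receptor CD44 (1.30 ± 0.18) and the peroxidase PRDX6 (1.34 ± 0.21) rose, and GCLC, which starts glutathione synthesis, fell (-1.41 ± 0.34). Of 18 iron handling genes, 5 rose and 3 fell (5 and 6 adjusted over the list alone; adjusted p = 0.399), with the iron regulatory protein ACO1 at 2.11 ± 0.22 and the biliverdin reductase BLVRA at -2.52 ± 0.42. Of 24 glutathione and NRF2 genes, 4 rose and 6 fell (6 and 7 adjusted over the list alone; adjusted p = 0.454). SRXN1, which repairs oxidized peroxiredoxins, rose by 2.93 ± 0.28 and the glutathione transferase MGST3 fell (-1.46 ± 0.26). For this list the median log2 change was 0.0067 and the mean -0.0117.

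More inflammatory genes rose than fell in IRI macrophage-like cells, and oxidative phosphorylation and cell cycle genes were called only as lower. Of 32 inflammatory cytokine and NF-kB genes, 15 rose and 2 fell (18 and 2 adjusted over the list alone; camera adjusted p = 1.11e-05, and adjusted p = 0.686 with an estimated correlation). IL10, an anti-inflammatory cytokine, rose from 19.9 ± 4.95 to 267 ± 98.5 CPM (log2 change 3.75 ± 0.29), CSF1, the macrophage growth factor, by 2.16 ± 0.31, OSM, a cytokine of the IL-6 family, by 1.48 ± 0.23 and NFKBIA, the NF-kB inhibitor, by 1.02 ± 0.16. Of 35 interferon response genes, 12 rose, 4 fell and 19 were not called (14 and 5 adjusted over the list alone; adjusted p = 0.0315, and 0.807 with an estimated correlation). The antiviral genes EIF2AK2 (2.59 ± 0.22), ISG15 (2.30 ± 0.22) and MX2 (1.73 ± 0.19) rose, and the chemokine CXCL10 fell (-2.98 ± 0.29). Of 43 nuclear-encoded oxidative phosphorylation genes, 19 fell and 0 rose (21 fell adjusted over the list alone; adjusted p = 0.00115, and 0.807 with an estimated correlation), among them the complex I genes NDUFB10 (-2.08 ± 0.26) and NDUFC2 (-2.45 ± 0.32). Of 21 proliferation genes, 13 fell and 0 rose (13 adjusted over the list alone; adjusted p = 0.000228, and 0.686 with an estimated correlation), with STMN1, a microtubule regulator of dividing cells, at -2.48 ± 0.33. None of these 4 lists passed fry (adjusted p = 0.0931, 0.313, 0.160 and 0.0931). The other macrophage lists missed the competitive test. Of 24 alveolar macrophage identity genes, 5 rose and 5 fell (5 and 6 adjusted over the list alone; adjusted p = 0.985). The lysosomal protease CTSB rose (1.36 ± 0.18), and GPNMB and the lipid receptor TREM2 fell (-2.52 ± 0.31 and -4.70 ± 0.64). For this list the median and mean were negative (-0.37 and -0.42) and the test pointed up. Of 33 hypoxia and glycolysis genes, 6 fell, including GAPDH (-1.16 ± 0.19) and P4HA1 (-1.99 ± 0.31), and 0 rose (5 adjusted over the list alone; adjusted p = 0.985), again with a negative median (-0.15) and a test that pointed up. T cell marker CD3E stood at 25.9 and 2.80 CPM in the IRI macrophage-like sums and at 2.70, 13.2 and 4.50 CPM in controls (without TMM scaling, as are the next values). ARG1, an enzyme high in monocyte- and neutrophil-like cells of the IRI CD45+ libraries, stood at 7033 and 2713 CPM in the IRI macrophage-like sums and at 669.6, 822 and 722 CPM in controls. CTSB, OSM, FDFT1 and ADAM8 were among the leading genes of monocyte-like or unnamed parts of cluster 11, so RNA or cells of that kind in the macrophage-like sums were not excluded as a source of their rise.

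By the rule for the largest changes, 10 genes led in each direction. The Y-linked gene ZFY was at least 162-fold higher in IRI, against 0 UMIs in controls. The interleukin receptors IL2RA and IL7R (5.17 ± 0.81 and 4.17 ± 0.59) rose, IL2RA with IRI levels of 112 ± 108 CPM. TMEM26 (4.58 ± 0.49), the sterol synthesis enzyme FDFT1 (3.97 ± 0.22, from 98.7 ± 24.2 to 1541 ± 78.4 CPM), EMP1 (3.84 ± 0.30), the metalloproteinase ADAM8 (3.80 ± 0.27), IL10, CD72 (3.73 ± 0.28) and the metal-binding MT1X (3.73 ± 0.50) followed. The 10 genes that fell most all had 0 IRI UMIs. The adhesion gene CTNNA3 was at least 148-fold lower (585 ± 95.2 CPM in controls), ZAN at least 55.2-fold, ZSWIM5 52.1-fold, FAM227A 40.6-fold, TMEM98 30.6-fold, EPM2A 28.4-fold, ANKFN1 24.0-fold, TENM1 23.3-fold, CAGE1 23.1-fold and RAB39A 21.2-fold. CTNNA3, ZAN, ZSWIM5 and ANKFN1 were also counted in the other immune and the structural classes of the controls. A counting difference between the library sets was not excluded as a source of their falls. IL7R and MT1X lost their calls without either IRI library (log2 changes of 3.85 and 4.37, and 3.64 and 3.76), as did RAB39A (adjusted p = 0.0774 and 0.0597), and TENM1 lost its call without IRI CD45+ replicate 1 (adjusted p = 0.0527). In all, 1221 of 10565 genes rose and 1779 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (3 controls, 2 IRI CD45+ libraries; 39 and 41 IRI cells against 252, 410 and 411 control cells). Cluster 13 held 78.4% of control and 83.8% of IRI macrophage-like cells. With genes spanning under 50 kb only, 732 rose and 818 fell, and with every sum thinned to the UMI total of the smallest 848 rose and 864 fell. In simulated data of this size the test found 17% of 2-fold and 67.0% of 4-fold changes.

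Whether macrophage-like cells changed in their own way was tested against T-like cells of the same libraries. Those lay mostly in different clusters in controls and IRI. CD69 and CTLA4 were among the leading genes of cluster 0 (81.2% of control T-like cells). CCR7, S1PR1 and LEF1 were among those of cluster 23 (73.9% in IRI), so a different mix of T-like cells was not excluded as a source. The change of IL10 was higher in macrophage-like cells by 5.16 ± 0.53 on the log2 scale (SE, n = 3 and 2, limma adjusted p = 0.0127), with a rise there and a fall in T-like cells (-1.43). The changes of the hemoglobin gene HBB (6.07 ± 0.86) and of the complement genes C1R (4.07 ± 0.39) and SERPING1 (4.01 ± 0.35) were also higher, and HBB and SERPING1 were not called in macrophage-like cells. In T-like cells HBB went from 329 to 0 CPM, C1R from 10.9 to 0.8 CPM and SERPING1 from 11.5 to 0.5 CPM, and the fibroblast collagen COL1A1 from 7.80, 23.0 and 53.2 CPM (without TMM scaling) to 0, so free RNA lost from the T-like sums was not excluded as their source. Fibronectin (FN1) and CXCL10 had lower changes (-6.70 ± 0.59 and -4.47 ± 0.52), as they fell in macrophage-like cells and rose in T-like cells. The change of ACSL4 was higher by 1.51 (adjusted p = 0.0352). Of 29 heat shock and unfolded protein genes, 4 were higher and 0 lower in this contrast (7 and 0 adjusted over the list alone; adjusted p = 2.20e-05, and 0.626 with an estimated correlation). Of 29 ferroptosis suppressors 5 were higher and 0 lower (5 adjusted over the list alone, camera adjusted p = 0.0186, and 0.626 with an estimated correlation). Of 26 drivers 3 were higher and 1 lower (5 and 1 adjusted over the list alone, adjusted p = 0.0269, and 0.626 with an estimated correlation). Other lists, such as the inflammatory and alveolar macrophage identity lists, also passed upward. Downward, of 43 oxidative phosphorylation genes 4 were lower and 0 higher (0 adjusted over the list alone, camera adjusted p = 0.00446, and 0.7 with an estimated correlation). Of 21 proliferation genes 3 were lower and 0 higher (8 lower adjusted over the list alone, adjusted p = 0.0159, and 0.7 with an estimated correlation). Of 9826 genes, 293 changed more upward and 675 more downward in macrophage-like than in T-like cells. With any 1 control left out no gene passed (1830 to 2010 genes at unadjusted p under 0.05), and without IRI CD45+ replicate 1 or 2 the counts were 688 and 2105, or 589 and 1678. Against monocyte-like cells 0 of 4924 genes passed (limma; 726 at unadjusted p under 0.05), and without control replicate 2, which leaves 1 control, it gave 42 higher and 866 lower. That contrast recovered 0% of simulated 4-fold changes, against 39.5% for the T-like contrast.

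T-, NK- and B-like cells of the IRI CD45+ libraries showed higher interferon response genes. In T-like cells 23 of 33 rose and 0 fell (23 adjusted over the list alone; adjusted p = 2.58e-07, and 0.859 with an estimated correlation), with EIF2AK2 at 2.30 ± 0.13 and MX2 at 2.60 ± 0.18. In NK-like cells 23 of 35 rose and 2 fell (23 and 3 adjusted over the list alone; adjusted p = 2.59e-06, and 0.551 with an estimated correlation), with PARP14 at 2.00 ± 0.11. In B-like cells 17 of 30 rose and 2 fell (17 and 2 adjusted over the list alone; adjusted p = 8.53e-05, and 0.721 with an estimated correlation), with MX2 at 2.14 ± 0.16. NK-like cells also had higher activation and cytotoxicity genes (13 of 29 rose and 5 fell, 13 and 5 adjusted over the list alone; adjusted p = 0.00886, and 0.679 with an estimated correlation), including the interleukin 2 receptor IL2RA (2.92 ± 0.14) and the protease GZMB (1.54 ± 0.10). Their proliferation genes fell (20 of 22, 21 adjusted over the list alone; adjusted p = 6.42e-10, and 0.551 with an estimated correlation), such as CDK1 (-1.99 ± 0.12). So did 30 of 43 oxidative phosphorylation genes, with 2 rising (31 and 2 adjusted over the list alone; adjusted p = 4.30e-05, and 0.551 with an estimated correlation), such as NDUFB7 (-1.50 ± 0.11). Clusters 1, 2 and 7 of the NK-like class also carried T markers, so its changes cannot be assigned to NK cells alone.

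Heat shock genes, which help proteins fold under stress, fell in 4 of the other immune classes. In T-like cells 20 of 30 fell and 1 rose (20 and 1 adjusted over the list alone; adjusted p = 5.50e-05, and 0.859 with an estimated correlation), with HSPB1 at -2.96 ± 0.15 and DNAJA1 at -2.27 ± 0.14. In B-like cells 17 of 29 fell and 3 rose (17 and 3 adjusted over the list alone; adjusted p = 0.00103, and 0.721 with an estimated correlation), with BAG3 at -2.23 ± 0.16. In plasma-like cells 17 of 29 fell and 2 rose (18 and 2 adjusted over the list alone; adjusted p = 3.80e-05, and 0.658 with an estimated correlation), with DNAJB1 at -3.03 ± 0.13. In mast/basophil-like cells 11 of 26 fell and 2 rose (11 and 2 adjusted over the list alone; adjusted p = 5.09e-05, and 0.385 with an estimated correlation), with DNAJB1 at -3.47 ± 0.26. Immediate-early genes, which cell isolation can induce, also fell in plasma-like cells (14 of 25, with 3 rising, as also adjusted over the list alone; adjusted p = 0.00498, and 0.688 with an estimated correlation) and in T-like cells (12 of 27, with 5 rising, as also adjusted over the list alone; adjusted p = 0.0487, and 0.876 with an estimated correlation), so a difference in handling between the library sets was not excluded. In dendritic-like cells 15 of 30 inflammatory genes rose and 4 fell (16 and 5 adjusted over the list alone; adjusted p = 0.000547, and 0.721 with an estimated correlation). NFKBIA was at 1.57 ± 0.14 there, and IL2RA rose by 6.49 ± 0.28. In monocyte-like cells 6 of 26 lysosome and phagocytosis genes rose and 0 fell (6 adjusted over the list alone; adjusted p = 0.00140, and 0.541 with an estimated correlation), among them the protease CTSB (2.66 ± 0.19), CD63 (1.51 ± 0.19) and CD68 (2.53 ± 0.45).

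Counts of called genes in these classes, by the same edgeR test of 3 controls against 2 IRI CD45+ libraries, were 3318 higher and 3581 lower in T-like cells, 3534 and 4405 in NK-like, 2126 and 2494 in B-like, 1616 and 2269 in plasma-like, 1325 and 1789 in dendritic-like and 328 and 395 in mast/basophil-like cells. Monocyte-like cells, with 2 controls of at least 20 cells, gave 274 higher and 428 lower. Without IRI CD45+ replicate 1 or 2 the monocyte-like counts were 241 and 211, or 216 and 205, and without control replicate 3 the mast/basophil-like counts were 176 and 246. T-like cells lay mostly in clusters 0 and 12 in controls and in clusters 23 and 29 in IRI, NK-like cells in clusters 2 and 1 against cluster 7, B-like cells in cluster 5 against cluster 18, and monocyte-like cells in different parts of cluster 11. A different mix of cells within these classes was therefore not excluded as a source of their changes. Neutrophil-like cells, with 3 to 9 cells per control, could not be tested. ARG1, the arginine-degrading enzyme of myeloid cells, stood at 60.6 and 177 CPM in IRI T-like cells, against 10834 and 7025 CPM in neutrophil-like cells of the same libraries and 2.70, 2.00 and 1.60 CPM in control T-like cells.

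A set of genes was lower in IRI in each of 6 immune classes. Of 8044 genes tested in macrophage-, T-, NK-, B-, plasma- and dendritic-like cells, 303 were at least 4-fold lower in all 6. Independent classes would give 0.002, but the classes come from the same libraries, so this value does not test the overlap. Each control set against the other controls gave 1, 0 and 0 such genes, and the IRI libraries on that scale 241. These genes took 2.63% of UMIs in controls and 0.126% in IRI CD45+ libraries. With the 3 controls summed and without TMM scaling, CTNNA3 stood between 372 and 581 CPM in macrophage-, dendritic-, T-, NK-, B-, plasma- and mast/basophil-like cells and in 4 structural classes. The median genomic span of the genes in the set with a symbol was 368.8 kb, against 30.5 kb for the other genes (permutation p = 1e-05, the smallest possible with 100000 permutations). The fifth of genes with the longest spans had median log2 changes of -1.06 in macrophage-, -1.27 in T- and -1.65 in NK-like cells. The medians were -1.09 in plasma-, -0.784 in dendritic-, -0.745 in B- and -0.478 in monocyte-like cells. In mast/basophil-like cells the fifth with the longest spans stood at -0.179 and that with the shortest at -0.188.

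**Figure D3:**
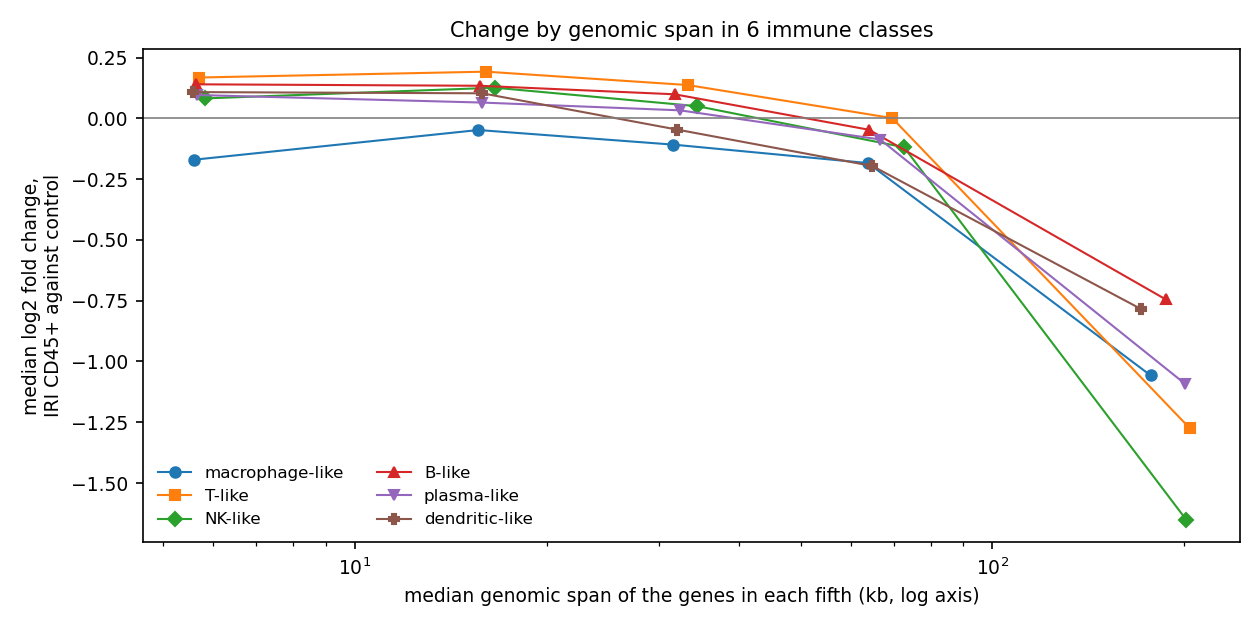
Median log2 fold change of IRI CD45+ against control (y axis) for genes in 5 equal groups by genomic span (x axis, median span of each group in kb, log scale) in 6 immune classes, 1 line per class. In the group of longest genes the median was -1.06 in macrophage-like, -1.65 in NK-like and -0.745 in B-like cells.

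The comparison of endothelial-like cells addresses how the vessel lining of the graft responded. VCAM1 and ICAM1, which bind leukocytes, rose in the IRI CD45- library: VCAM1 from 35.5 ± 12.2 CPM (SD, n = 3 controls) to 487 CPM (log2 change 3.74 ± 0.41, SE, edgeR adjusted p = 2.40e-11) and ICAM1 from 579 ± 97.6 to 2747 CPM (2.24 ± 0.33, adjusted p = 1.41e-07). The growth factor receptor KDR rose by 1.68 ± 0.36 (adjusted p = 0.000216) and the junction protein CLDN5 by 1.33 ± 0.33 (adjusted p = 0.00161). VWF, the platelet-binding factor, fell (-1.57 ± 0.41, adjusted p = 0.00224). It spans 139.3 kb, and genes of long span were lower in this comparison too. The fifth with the longest spans had a median log2 change of -0.766, the next -0.209 and the shortest 0.04. A counting difference between the library sets was therefore not excluded as a source of the fall of VWF. CDH5, the adherens junction cadherin, stood at 1006 ± 111 CPM in controls and 1330 CPM in IRI (adjusted p = 0.413). SELE had no feature of that name and SELP too few UMIs. VCAM1 lies on chromosome 4 from 117496914 to 117511211. There was 1 IRI CD45- library, so each p compares it with the spread of the 3 controls. The call of CLDN5 was lost without control replicate 3 (log2 change 1.26).

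**Figure D4:**
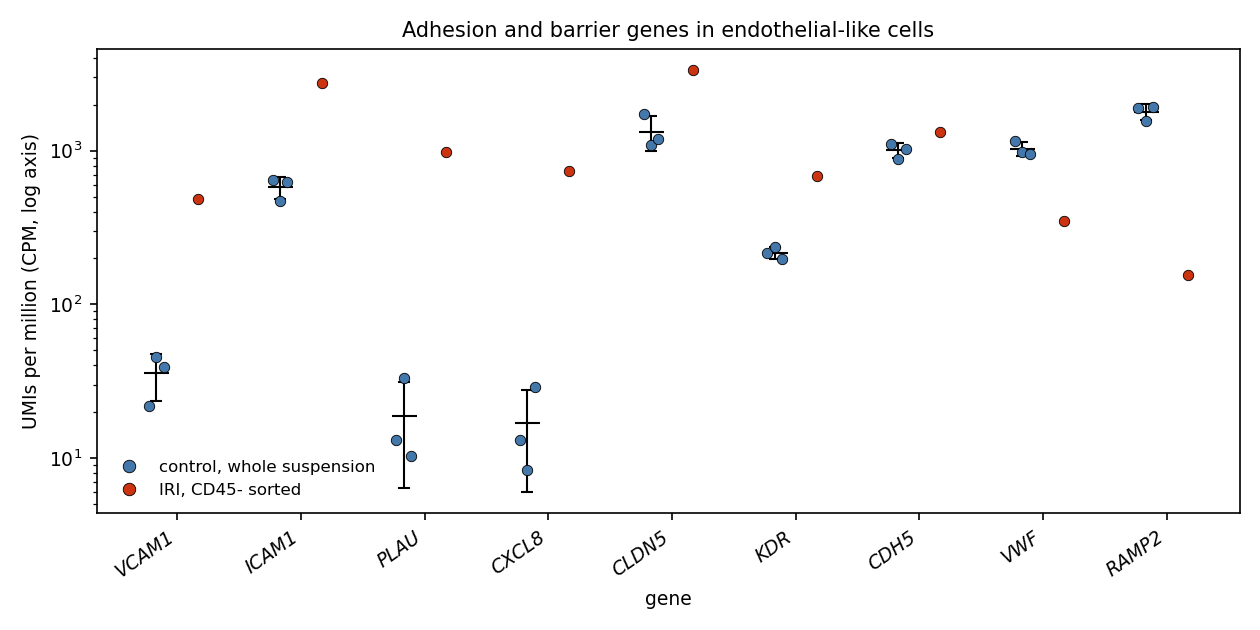
Scaled UMI counts (CPM, y axis, log scale) of 9 adhesion, activation and barrier genes (x axis) in endothelial-like cells. Points are libraries, 3 controls and 1 IRI CD45-; black bars are the mean and SD of the controls. VCAM1 stood at 487 CPM in IRI and averaged 35.5 CPM in controls, and RAMP2 at 156 and 1798 CPM.

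Of 24 endothelial activation and adhesion genes, 11 rose and 2 fell (12 and 2 adjusted over the list alone; adjusted p = 5.03e-07, and 0.399 with an estimated correlation), with the fibrinolysis gene PLAU at 5.80 ± 0.43. Of 24 inflammatory genes, 19 rose and 0 fell (22 adjusted over the list alone; adjusted p = 1.91e-16, and 0.399 with an estimated correlation). The neutrophil chemokine CXCL8 rose by 5.25 ± 0.43, NFKBIA by 3.23 ± 0.30 and the granulocyte growth factor CSF3 by a ratio of 258 (95% counting interval 70.4 to 2148, on 2 control UMIs). Of 31 heat shock genes, 16 rose and 0 fell (17 adjusted over the list alone; adjusted p = 2.40e-06, and 0.4997 with an estimated correlation), with CRYAB at 4.69 ± 0.38 and BAG3 at 2.39 ± 0.36. Of 32 interferon response genes, 12 rose and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 0.00297, and 0.722 with an estimated correlation), with MX2 at 2.99 ± 0.38. Of 28 barrier and identity genes, 5 rose and 7 fell (5 and 9 adjusted over the list alone; adjusted p = 0.130). RAMP2, a receptor component that protects the barrier, fell (-3.53 ± 0.46). SOX18, a vascular transcription factor, was lower by a ratio of 62.7 (11.11 to 2489, on 1 IRI UMI). Of 23 ferroptosis drivers and markers, 6 rose and 2 fell (7 and 2 adjusted over the list alone; adjusted p = 0.0522), with the stress regulator ATF4 at 2.40 ± 0.32 and PTGS2 at 3.81 ± 0.56. Estimated free RNA of AT2- and secretory-like cells equalled at most 16.8% of the IRI level of CSF3 and 8.88% of CXCL8, and under that for the other genes named here. Free RNA of other cells was not estimated. Part of cluster 30, with 24 of the endothelial-like cells, had OSM and CXCL8 among its leading genes, as did the neutrophil-like cluster 19. RNA or cells of that kind were not excluded as a source of the inflammatory rises.

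Most of the largest rises in endothelial-like cells were epithelial transcripts. The surfactant gene SFTPC rose by 10.15 ± 0.44 (12.6 ± 10.9 to 12790 CPM). The estimate of free RNA is scaled to this gene and so cannot test it. EPCAM (at least 83.5-fold higher), SFTPD (50.7-fold), KRT8 (41.8-fold), KRT18 and WFDC2 (28.8-fold each) had estimated free RNA of 132%, 97.3%, 144%, 84.0% and 94.7%, and S100A2 (ratio 331, 58.2 to 13200, on 1 control UMI) 107%. For the collagenase MMP1 (at least 55.7-fold higher) and the stress-induced transcription factor FOSL1 (at least 31.8-fold) the estimates were 0.819% and 14.7%. The 10 largest falls all had 0 IRI UMIs: COL19A1 (at least 66.1-fold lower), CTNNA3 (54.6-fold), CLEC1B (21.3-fold), ZAN (20-fold), PODN (16.2-fold), ST6GALNAC3 (16.0-fold), ZSWIM5 (14.1-fold), ROBO2 (13.4-fold), TMEM9B (12.7-fold) and ANKFN1 (12.2-fold). In the summed controls COL19A1 stood at 536 to 1252 CPM across immune and structural classes, and CTNNA3, ZAN, ZSWIM5 and ANKFN1 were counted in all of these too. COL19A1, CTNNA3, ST6GALNAC3, ZSWIM5, ROBO2 and ANKFN1 span 187.9 to 1779.3 kb, and CLEC1B, ZAN, PODN and TMEM9B 7.1 to 47.6 kb. A counting difference between the library sets was not excluded as a source of these falls. In all, 929 of 6692 genes rose and 772 fell (3 controls with 80, 70 and 190 cells, 1 IRI library with 311), and 860 and 593 with genes of high epithelial background left out. Control cells lay in cluster 4 and IRI cells in part of cluster 30. DESeq2 called 388 and 239, genes spanning under 50 kb gave 485 and 343, and without control replicate 3 there were 612 and 383.

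Inflammatory genes also rose in fibroblast-, lymphatic endothelial- and smooth muscle/pericyte-like cells of the IRI CD45- library, each compared as the endothelial-like cells were. In fibroblast-like cells 21 of 30 rose and 0 fell (22 adjusted over the list alone; adjusted p = 5.27e-18, and 0.331 with an estimated correlation), with the cytokine LIF at 8.52 ± 0.33 and the monocyte chemokine CCL2 at 4.54 ± 0.22. Their ferroptosis drivers and markers rose in 11 of 29 cases and fell in 3 (12 and 3 adjusted over the list alone; adjusted p = 0.000361, and 0.331 with an estimated correlation), with the stress genes TRIB3 (5.27 ± 0.21) and ATF4 (3.33 ± 0.21) and with ACSL4 (2.80 ± 0.20). Of their 33 ferroptosis suppressors, 11 rose and 3 fell (12 and 6 adjusted over the list alone, camera adjusted p = 0.0331, and 0.750 with an estimated correlation). In smooth muscle/pericyte-like cells 7 of 16 suppressors rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.00348, and 0.372 with an estimated correlation). In ciliated-like cells 7 of 18 suppressors rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.00677, and 0.723 with an estimated correlation). In lymphatic endothelial-like cells 15 of 21 inflammatory genes rose and 0 fell (15 adjusted over the list alone; adjusted p = 3.69e-13, and 0.324 with an estimated correlation), with CCL2 at 5.94 ± 0.20. CCL2 was among the leading genes of AT2-like clusters 24, 25 and 32 and of fibroblast-like parts of cluster 27. It was not among those of the lymphatic part of cluster 30. Free RNA of AT2-like or other cells was thus not excluded as a source of its rise in lymphatic cells. In smooth muscle/pericyte-like cells 19 of 25 rose and 0 fell (19 and 1 adjusted over the list alone; adjusted p = 3.87e-16, and 0.356 with an estimated correlation), with PTX3, a soluble pattern receptor, at 6.12 ± 0.47. The metallothioneins MT1A (at least 438-fold) and MT1X (9.48 ± 0.46) were higher there too. Ciliated-like cells had only 2 controls of at least 20 cells, and 14.3% of the calls were false in simulated data of their size. There 14 of 31 heat shock genes rose and 0 fell (15 and 1 adjusted over the list alone; adjusted p = 1.16e-06, and 0.723 with an estimated correlation), with BAG3 at 3.33 ± 0.46, and 7 of 19 glutathione and NRF2 genes rose and 0 fell (7 and 1 adjusted over the list alone; adjusted p = 0.00331, and 0.723 with an estimated correlation), with GPX1 at 2.23 ± 0.45. Counts of genes higher and lower were 2049 and 2394 in fibroblast-like, 946 and 1015 in lymphatic endothelial-like, 1036 and 756 in smooth muscle/pericyte-like and 633 and 435 in ciliated-like cells. Without control replicate 3 smooth muscle/pericyte-like cells had 617 and 431. Fibroblast-like cells lay in cluster 9 in controls and in parts of cluster 27 in IRI, and lymphatic cells in cluster 22 and in part of cluster 30. Of smooth muscle/pericyte-like cells 60.2% lay in cluster 15 in controls and 86.5% in 1 part of cluster 27 in IRI, and ciliated-like cells lay in different parts of cluster 20. SFTPC stood at 9.61% of its AT2-like level in fibroblast-like, 7.48% in lymphatic, 10.02% in smooth muscle/pericyte-like and 6.79% in ciliated-like cells of the IRI CD45- library.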

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

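The tests of explanations below were chosen only after the result was seen, except the slope of UMIs on cell totals for the genes lower in 6 classes; the contrast of macrophage- with T-like cells was chosen before the data were examined. The change from control to IRI CD45+ libraries differed between macrophage-like and T-like cells for 293 genes that changed more upward and 675 that changed more downward in macrophage-like cells, a difference between cell types under the same contrast. T-like cells lay mostly in different clusters in the control and IRI libraries. With any 1 control left out the counts were 0 and 0 (limma; 1830 to 2010 genes at unadjusted p under 0.05), and without IRI CD45+ replicate 1 or 2 they were 688 and 2105, or 589 and 1678. In the IRI CD45- library, whose neutrophil-like cells no comparison used, 17.5% of the 1994 immune-named cells (348 cells) were neutrophil-like, above the 0.122% of the controls. With the stricter cell filter they were 135 of 1462 (9.23%), and with the finer clustering 229 of 1908; the controls hold no cell under 1001 UMIs.

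Of 8044 genes, 303 were at least 4-fold lower in all 6 immune classes of the IRI CD45+ libraries. Free RNA in the control libraries would add a like number of UMIs to small and large cells, and the slope of log UMIs of these genes on log total UMIs in control T-like cells was 0.793 to 0.826, against 1.06 to 1.12 for CD3E. HBB, a red cell transcript that T-like cells can hold as free RNA, had slopes of 1.36, 1.01 and -0.183, so the slope does not separate the 2 sources, and free RNA cannot be told apart from RNA of the cells. Reads over introns counted in the controls and not in the IRI libraries may explain many of them, since their median span was 368.8 kb against 30.5 kb for other genes. A response to ischemia and reperfusion cannot be told apart from this, because the group and the counting differ together; 60 of the 111 genes tested were also at least 4-fold lower in all 4 structural classes.

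Y-linked transcripts ZFY, EIF1AY and KDM5D gave 10, 16 and 10 UMIs in the controls and 1174, 1103 and 1770 UMIs in the IRI CD45+ and CD45- libraries. A counting difference between the library sets cannot be told apart: 0.41% of 9771 other genes stood under 5% of their IRI level in the controls, but a difference limited to some genes stays open. Another 399 genes were listed in every IRI library and no control. ZFY, EIF1AY and KDM5D are not among them, as each had UMIs in at least 1 control. The Y-linked gene AMELY went the other way, listed in every control (0.078, 0.119 and 0.061 CPM) and in no IRI library. At such low levels it does not decide between the explanations. Animals of different sex in the control and IRI libraries are a candidate explanation, with Y-linked UMIs in 17 of 17 named classes of at least 20 cells of the IRI CD45- library, the graft's own AT2-like cells (988 UMIs) included. A counting difference would give Y-linked UMIs in every class as well, so this does not favour a sex difference over it. The labels give no sex. Since they take the controls from donors' right lungs, a sex difference would mean that the control lungs were not those of the donors of these grafts, and it would be confounded with injury in every comparison.

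Epithelial transcripts rose in endothelial-like cells of the IRI CD45- library. Doublets with AT2-like cells would leave most cells free of SFTPC, and 100.0% of 311 endothelial-like cells held it, with a median of 8 UMIs against 244 in AT2-like cells, which argues against doublets as the main source. Free RNA of AT2-like cells may account for the pattern: without TMM scaling SFTPC stood at 10388 CPM, 9.08% of its AT2-like level, SFTPB at 8.87%, NAPSA at 9.13% and SFTPA1 at 6.06%. No biological explanation was tested.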

How the results depend on the processing

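Genes spanning under 50 kb, the IRI CD45- library added as an IRI library, cluster 13 only, genes counted in any IRI library, genes of high epithelial background left out and removal of the top 6% of doublet scores were chosen only after the results were seen; the other alternatives were chosen before the data were examined. The 136 named gene results gave 2117 values under alternatives, of which 2073 kept direction and side of the threshold, 26 lost and 17 gained a call, and 1 reversed. The reversed one is FTL in macrophage-like cells, not called in any case, whose log2 change ran from -0.276 to 0.083 over left-out replicates. Of 90 share values, 89 kept their sign. The mast/basophil-like share difference ran from -0.0672 to 0.984 percentage points over left-out replicates, negative without IRI CD45+ replicate 1. The T-like difference ran from 2.87 to 13.8 and the B-like difference from 1.56 to 4.46 percentage points over left-out replicates. With called doublets kept the monocyte-like difference was 2.90 percentage points, against 4.88, and the groups overlapped. No share could pass the threshold by the exact permutation test at this number of libraries.

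Counts of called genes moved by over 1.5 times as follows. With genes spanning under 50 kb, macrophage-like cells had 732 genes higher and 818 lower, endothelial-like cells 485 and 343, and the macrophage minus T contrast 336 lower. Calls then numbered 293 in monocyte-, 3017 in T-, 3433 in NK-, 2180 in B-, 1702 in plasma-, 1383 in dendritic-, 414 in mast/basophil-, 1144 in lymphatic endothelial-, 2435 in fibroblast-, 1013 in smooth muscle/pericyte- and 444 in ciliated-like cells; fewer genes were tested. Macrophage- and monocyte-like cells together gave 2387 higher and 3129 lower. Monocyte-like cells were 397 of these in IRI, beside 80 macrophage-like, and 65 in controls, beside 1073, so cell type differs between the groups there. Without the low-count filter monocyte-like cells had 541 genes higher. Thinned to the smallest library, macrophage-like cells had 848 higher and 864 lower, with fewer genes tested, and with a replicate block 1172 lower; with that block dendritic-like cells had 1861 calls and mast/basophil-like cells 198 higher, and the cause was not tested. The DESeq2 Wald test called 475 genes in mast/basophil-like, 388 higher and 239 lower in endothelial-like, 712 in lymphatic endothelial-like, 2618 in fibroblast-like, 696 in smooth muscle/pericyte-like and 347 in ciliated-like cells; the cause was not tested. With genes of high epithelial background left out, fibroblast-like cells had 1540 lower, with fewer genes tested. The DESeq2 fit, which changes scaling and test together, moved the log2 changes in fibroblast-like cells by a median of 0.107.

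Over left-out replicates, calls ran from 421 (without IRI CD45+ replicate 2) to 577 (without control replicate 2) in monocyte-like (198 to 215 lower), 422 (without control replicate 3) to 667 in mast/basophil-like (188 higher without IRI CD45+ replicate 1) and 1048 (without control replicate 3) to 2172 in smooth muscle/pericyte-like cells. Endothelial-like cells had 612 to 1185 higher and 383 to 976 lower, both lowest without control replicate 3. The macrophage minus T contrast had 0 to 688 higher and 0 to 2105 lower, at 0 with any 1 control left out (limma; 1830 to 2010 genes at unadjusted p under 0.05). The macrophage minus monocyte contrast had 0 to 42 higher and 0 to 866 lower, highest without control replicate 2, and 1 higher and 95 lower with a prior count of 0.5. Monocyte-like cells had 2 controls of enough cells, so leaving out either left 1 control, and leaving out control replicate 3 gave no value of its own. A lone library was assumed to vary like the other group. The cause of these moves was not tested.

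With an estimated correlation 0 lists were called in macrophage-like cells, 0 in endothelial-like cells, 0 in the other immune classes, 0 in the other CD45- classes and 0 in the macrophage minus T contrast. The fry test called 1 list in macrophage-like and 1 in endothelial-like cells, 27 in the other immune classes and 25 in the other CD45- classes. In macrophage-like cells the edgeR test found 17% of simulated 2-fold changes, against 57.1% in T-like cells with the same number of libraries. What limits the macrophage-like comparison was not tested.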

Other observations

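Calls of ribosomal protein genes differed in direction between some immune classes of the IRI CD45+ libraries. In mast/basophil-like cells 18 of 37 fell and 0 rose (18 adjusted over the list alone; camera adjusted p = 2.98e-07, and 0.904 with an estimated correlation). In monocyte-like cells 14 of 37 rose and 0 fell (21 and 1 adjusted over the list alone; adjusted p = 7.91e-06, and 0.541 with an estimated correlation), and in T-like cells 20 rose and 7 fell (20 and 7 adjusted over the list alone; adjusted p = 0.00877, and 0.876 with an estimated correlation), as did 17 in dendritic-like cells, where 8 fell (17 and 8 adjusted over the list alone; adjusted p = 0.0118, and 0.979 with an estimated correlation). The list missed the test in macrophage-, NK-, B- and plasma-like cells (adjusted p = 0.706, 0.156, 0.789 and 0.988), and fry called it in none of these 8 classes (adjusted p = 0.0759 to 0.949). The difference between classes was not tested. In NK-like cells 20 of 25 extracellular matrix genes fell and 2 rose (21 and 2 adjusted over the list alone; adjusted p = 0.00207, and 0.679 with an estimated correlation). COL1A1, a collagen of fibroblasts, stood at 7.80, 23.0 and 53.2 CPM in control T-like cells and at 0 in those of both IRI CD45+ libraries.

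Neutrophil-like cells, which had too few cells in the controls for a test, held ARG1 at 10834 and 7025 CPM in the IRI CD45+ libraries. S100A12, a calcium-binding protein of neutrophils, stood at 5200 and 5618 CPM there and at 44640, 32942 and 24763 CPM in the 3 to 9 control cells. Monocyte-like cells held ARG1 at 16786 and 11340 CPM in the IRI CD45+ libraries and at 2051, 1496 and 137 CPM in the controls. In the IRI CD45- library AT2-like cells carried SFTPC at 114376 CPM, and secretory-like cells carried SCGB1A1, the club cell secretory protein, at 78930 CPM. Of the 547 unnamed cells of the IRI CD45+ libraries, 308 and 192 lay in parts of cluster 11, which also held the monocyte-like cells.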
